A study of Xenopus laevis with 18 samples.

How the data were processed

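RNA was extracted with TRIzol from the cytosol, ER and pellet of 4 oocytes or 4 eggs per library, after 5 spike-in RNAs (egfp, mCherry, mRuby2, firefly and renilla) had been added to each fraction, per the labels. Ribosomal RNA was depleted, stranded libraries were made and all were sequenced on a single NovaSeq lane with 101 cycles per end, per the labels. The authors demultiplexed with bcl2fastq 2.20 and quantified transcripts with kallisto 0.46.2, per the submitters' processing notes. The transcript set and the genome build were not given in the sources used here, so no coordinates are printed. The deposited library tables give estimated counts, transcript lengths and TPM for 51032 transcripts, 5 of which are the spike-ins. Of the estimated counts 65.5 to 71.9% per library were whole numbers. The authors converted TPM to attomolar concentrations by regression on the spike-ins, per the labels. In the deposited table each library's attomolar value is a power of its TPM, with exponents of 0.981 to 1.10, and the 3 fractions of each stage and replicate number sum to the same total. The deposited percent values are each fraction's share of a transcript's attomolar total, and the authors' ratio columns divide group means of attomolar values. The authors also deposited a q-value for each ratio, from a test not given in the sources used here, and classes of transcripts along the animal-vegetal axis. Another 22 columns of the series tables, such as means and totals, were not used here.

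Samples were grouped by the stage and fraction in their labels, 3 libraries in each of 6 groups. Estimated counts were rounded to whole numbers, and 1 transcript without a name was left out. Spike-ins were kept out of library sizes and tests. Transcripts were filtered with filterByExpr by group, which left 25938, and tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, glmQLFit and glmQLFTest) in 1 fit over all 18 libraries with 12 residual degrees of freedom. Transcripts were called at a Benjamini-Hochberg adjusted p under 0.05. TMM sets the typical transcript to no change, so each log2 fold change is relative to it. The 11 comparisons were ER, pellet and cytosol with each other within a stage, egg with oocyte within a fraction, and 2 interactions that ask whether the ER to cytosol or pellet to cytosol difference changed between stages. Comparisons that share a group of libraries share its chance values. Sums of attomolar values and shares of transcripts were compared with two-sided exact permutation tests, where 3 against 3 cannot give a p under 0.1. CPM levels and percentages are means with SD over 3 libraries. Libraries held 23151603 to 37863318 counts. In counts simulated at this depth for oocyte ER against cytosol, with 200 of 25938 transcripts changed, the edgeR test recovered 54.7% of changes of 1.5-fold, 73.9% of 2-fold and 86.6% of 4-fold, and 8.28% of its calls were unchanged transcripts. Far more transcripts were called in the data, where these shares may differ.

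The tests of the comparisons and of the lists, the gene lists, the named-gene rule and all alternatives but one were chosen before the data were examined, and most tests of explanations after. The rule took, in each comparison, the 5 highest and 5 lowest log2 fold changes among called transcripts with a gene symbol, a mean log2 CPM of at least 5 and no overlap between the libraries compared, the 2 members of each list with the smallest adjusted p in each direction, and a fixed panel (gdf1, vegt, wnt11b, velo1, dazl, nanos1, ddx25, plin2, trim36, mos, ccnb1, aurka, wee1, hspa5 and gapdh). Which of the list members and panel genes so named are printed was decided after their values were seen. Symbols come from the deposited tables. The L and S homeologs of this allotetraploid are separate transcripts (12916 L and 9559 S), and 2544 transcripts share a symbol with another. Reads of near-identical homeologs or copies can be split between them by the quantification, so their single values are uncertain.

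The gene lists covered secreted ligands and extracellular proteins, membrane receptors and adhesion proteins, the egg coat, ER resident and translocon proteins, ER shaping proteins, cytosolic ribosomal proteins, the proteasome, glycolysis, the actin and tubulin cytoskeleton, nuclear-encoded oxidative phosphorylation, mitochondrial ribosomal proteins, mitochondrial genome transcripts, vegetal and germ plasm RNAs, animal pole RNAs, meiotic maturation and cell cycle, maternal mRNA storage, maternal transcription factors and Wnt axis, histones, follicle cell markers, and blood, immune and liver markers. Both homeologs counted. Of the 20 lists, that of mitochondrial genome transcripts matched no symbol and 19 were tested. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 209 tests, and with fry. List medians were also computed with members at 0 in all libraries of a group set to a bound of 3 counts per library.

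Replicate numbers were checked for pairing on 8919 transcripts, by correlating the deviations of same-numbered libraries from their group means. Every pair exceeded 0.1 for egg cytosol with egg pellet (r = 0.122 to 0.450) and egg ER with egg pellet (r = 0.371 to 0.711). Pairs of unlike number reached 0.219 for egg cytosol with egg pellet and 0.482 for egg ER with egg pellet. Both exceed some same-numbered pairs, so pairing by number stays uncertain, and the labels give no shared animal or batch. The authors' totals and percentages join same-numbered fractions, which may point to pairing. Percentages and shares here, and any tests of them, rest on that joining, while the main fit is unpaired. Alternatives were DESeq2 1.42.0, edgeR with library size alone, edgeR scaled by summed spike-in counts, limma on log2 attomolar values with a pseudocount of 0.00111, no low-count filter, only the groups compared, a replicate block of 2 kinds, and each library left out in turn. Leaving out 3 libraries that stood apart was added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the remaining steps.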

Results

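RNA was sequenced from the cytosol, the endoplasmic reticulum (ER) and the pellet of Xenopus laevis stage VI oocytes, the full-grown immature female germ cell arrested in prophase of meiosis, and of mature eggs, obtained by culturing such oocytes with 2 µM progesterone at 18 °C. Each fraction came from 4 defolliculated cells and received 5 spike-in RNAs before extraction. The 18 libraries made 6 groups of 3 replicates, called biological replicates in the study's design. Which frog or culture each came from is not given in the sources used here, so p-values measure the spread between these samples, which may be technical. Libraries held 35391190 to 37863318 estimated counts in oocyte cytosol, 27433721 to 29792589 in oocyte ER, 27458966 to 29591821 in oocyte pellet, 27708411 to 37358436 in egg cytosol, 23151603 to 27827907 in egg ER and 32989620 to 33823969 in egg pellet. Replicates correlated across transcripts at r = 0.993 to 0.997 of log2 TPM, and no pair agreed within sampling noise, with a chi-square per degree of freedom of at least 3.58. A single transcript model, ccdc50.L (571 nucleotides), took 16.9 to 17.8% of all TPM in the oocyte ER libraries and 21.9 to 29.6% in the egg ER libraries, the highest value being that of egg ER replicate 1. Its sequence was not examined, so whether its reads came from ccdc50 mRNA or from another RNA matched to the model is open, here and wherever ccdc50.L is named. The first principal component held 49.4% of the variance and parted pellets from the other fractions, the second 12% and parted ER from the other fractions.

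The amount of RNA was compared between fractions relative to the spike-ins. Of these egfp made up 81.6 to 89.7% of spike-in counts and 88.4 to 93.8% of spike-in TPM in each library, with 15 to 253 firefly and 3 to 39 renilla counts, so values scaled by summed spike-ins rest mostly on 1 RNA. On the authors' attomolar scale the cytosol held 1.25 times as much RNA in eggs as in oocytes (39734 ± 3841 against 31720 ± 2337 aM, SD, n = 3, exact two-sided permutation p = 0.1), but 1.13 times with overlapping libraries by TPM over spike-in TPM (exact p = 0.5). The ER held 0.678 times as much (20238 ± 365 against 29848 ± 3385 aM, exact p = 0.1). A p of 0.1 is the smallest that 3 against 3 samples allow. Without the 20 most abundant transcripts the ER ratio was 0.587, and over the median transcript the cytosol ratio was 1.53. The pellet differed by less than the spread between replicates (10684 ± 3757 against 9089 ± 3017 aM, exact p = 0.5). Its ratio of 1.18 became 0.937 without egg pellet replicate 1. In oocytes the ER held 0.941 times the RNA of the cytosol (exact p = 0.5) and the pellet 0.287 times (exact p = 0.1), and in eggs 0.509 and 0.269 times (exact p = 0.1 for both). Over the median transcript the ER to cytosol ratios were 0.671 and 0.279 (exact p = 0.1 for both), and the egg pellet ratio was 0.164. Of the RNA recovered, oocytes had 44.9 ± 3.31% in the cytosol, 42.2 ± 4.79% in the ER and 12.9 ± 4.27% in the pellet, and eggs 56.2 ± 5.44%, 28.6 ± 0.517% and 15.1 ± 5.32% (SD over replicate numbers, n = 3, not tested). The median transcript with at least 1 TPM in every library of the group had 33.6% of its copies in the oocyte ER (quartiles 29.6 and 38.1%, 19209 transcripts) and 18.8% in the egg ER (quartiles 16.7 and 21.3%, 18810 transcripts). The authors' values sum to the same total for each stage and replicate number, so these figures compare how RNA was distributed, not how much a cell held. In the authors' deposited table, 2920 transcripts were higher and 345 lower in egg than oocyte cytosol at a q-value under 0.05, and 129 were higher and 10175 lower in egg than oocyte ER. The same table had 12595 transcripts higher in cytosol than ER and 1071 lower in oocytes, against 21313 and 118 in eggs.

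**Figure D1:**
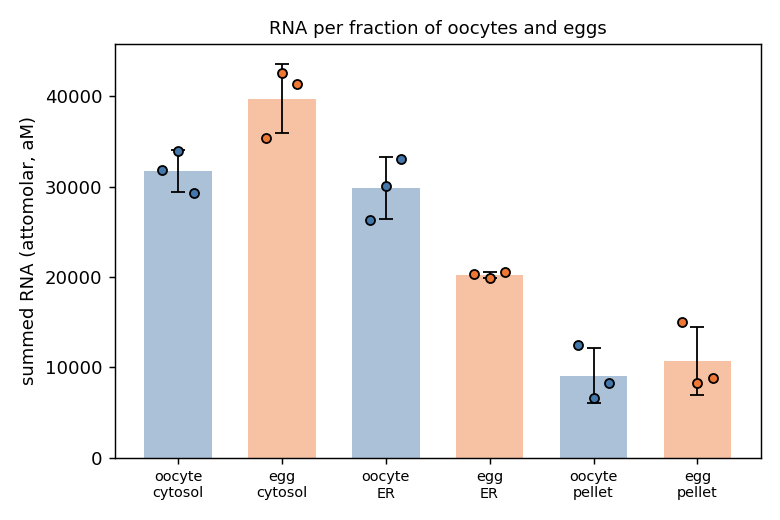
Summed RNA of each fraction on the authors' attomolar scale (y axis, aM) for the cytosol, ER and pellet of oocytes and eggs (x axis). Points are single libraries, bars the mean of 3 and lines ± 1 SD. Egg ER libraries lie between 19850.6 and 20575.6 aM, below the oocyte ER libraries at 26343.2 to 33099.8 aM.

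Transcripts that the authors' tables class by their position along the animal-vegetal axis of the egg differed in distribution. In oocytes the 26 extremely vegetal transcripts had on average 67.2 ± 6.61% of their copies in the pellet and 16.8 ± 1.92% in the cytosol, and in eggs 23 ± 10.6% and 58.9 ± 7.04% (SD, n = 3, exact p = 0.1 for both fractions, the smallest possible). The 133 vegetal transcripts went from 39.2 ± 8.10% to 15 ± 8.03% in the pellet and from 33 ± 3.44% to 65.2 ± 5.57% in the cytosol (exact p = 0.1 for both). The 286 extremely animal transcripts had 20.3 ± 6.36% in the oocyte pellet and 20.7 ± 8.01% in the egg pellet (exact p = 0.9), while their ER part went from 41 ± 3.83% to 22.9 ± 4.08% and their cytosol part from 38.7 ± 3.82% to 56.4 ± 4.03% (exact p = 0.1 for both). The 10710 animal transcripts had 34.3 ± 2.43% and then 19.3 ± 2.53% in the ER, and 52.6 ± 3.45% and then 67.1 ± 4.22% in the cytosol (exact p = 0.1 for both). The 135 transcripts of the class named other went from 42.6 ± 3.12% to 64.8 ± 4.54% in the cytosol (exact p = 0.1), with 23.5 ± 6.58% and then 14.4 ± 7.09% in the pellet (exact p = 0.3).

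Which mRNAs sit with the ER of the oocyte was asked by comparing ER with cytosol. Of 25938 transcripts tested, 6294 were higher in the ER and 6423 lower, relative to the typical transcript. Here and in each comparison, transcripts named as highest or lowest are called ones with a symbol, a mean log2 CPM of at least 5 and no overlap between libraries. The highest log2 fold changes (± standard error) were 5.61 ± 0.41 for ccdc50.L (gene47265), a model whose RNA is uncertain, 4.64 ± 0.10 for mprip.L, a myosin phosphatase partner, 4.18 ± 0.14 for lima1.S, an actin-binding protein, 4.11 ± 0.11 for prrg4.L, a transmembrane protein, and 4.06 ± 0.11 for spata13.S, a guanine nucleotide exchange factor. The ccdc50.L level was 24550 ± 894 CPM in the ER and 503 ± 246 in the cytosol (SD, n = 3). Its adjusted p was 2.1e-10. The lowest were -3.38 ± 0.15 for parp2.L (gene20034), a DNA repair polymerase, -2.03 ± 0.34 for smad4.1.S, a mediator of TGF-beta signalling, -1.83 ± 0.07 for sptan1.S, a spectrin chain, -1.66 ± 0.08 for utrn.L and -1.61 ± 0.06 for pmfbp1.L. Nuclear-encoded oxidative phosphorylation mRNAs had 105 of 122 members higher and 1 lower (110 and 1 adjusted over the list alone), with a median of 0.58. Spike-in scaling gave -0.23 as median with 4 higher and 18 lower, and limma on attomolar values -0.033 with 4 and 2. They included cox4i2.S (2.45 ± 0.09) and atp5f1c.L (1.40 ± 0.07); the list had a camera adjusted p of 4.7e-18 and adjusted p = 0.25 with an estimated correlation. Mitochondrial ribosomal protein mRNAs had 66 of 97 members higher and 1 lower (70 and 1 adjusted over the list alone), with a median of 0.39. Spike-in scaling gave -0.44 as median with 2 higher and 31 lower, and limma on attomolar values -0.24 with 2 and 2. Among these, mrpl15.L stood at 1.47 ± 0.05 and mrpl38.L at 1.40 ± 0.06; the list had a camera adjusted p of 5.4e-10 and adjusted p = 0.25 with an estimated correlation. ER resident and translocon mRNAs had 60 of 116 members higher and 19 lower (61 and 20 adjusted over the list alone), with a median of 0.21. Spike-in scaling gave -0.60 as median with 1 higher and 63 lower, and limma on attomolar values -0.42 with 1 and 24. Here ssr1.L, a translocon-associated protein, was at 3.62 ± 0.09, p4hb.L, a protein disulfide isomerase, at 1.10 ± 0.05 and the stress sensor ern1.S at -0.96 ± 0.08; the list had a camera adjusted p of 1.4e-04 and adjusted p = 0.20 with an estimated correlation. Vegetal and germ plasm RNAs had 29 of 37 members higher and 3 lower (29 and 3 adjusted over the list alone), with a median of 0.91. Spike-in scaling gave 0.10 as median with 4 higher and 7 lower, and limma on attomolar values 0.28 with 5 and 2. One of them, dand5.S, a secreted antagonist, was at 3.16 ± 0.13; the list had a camera adjusted p of 1.3e-09 and adjusted p = 0.25 with an estimated correlation. Cytosolic ribosomal protein mRNAs had 69 of 124 members higher and 5 lower (72 and 5 adjusted over the list alone), with a median of 0.29. Spike-in scaling gave -0.51 as median with 0 higher and 60 lower, and limma on attomolar values -0.37 with 0 and 12; the list had a camera adjusted p of 2.8e-06 and adjusted p = 0.55 with an estimated correlation. For secreted ligands and extracellular proteins there were 28 of 72 members higher and 17 lower (29 and 17 adjusted over the list alone), with a median of 0.29. Spike-in scaling gave -0.51 as median with 5 higher and 31 lower, and limma on attomolar values -0.26 with 6 and 17. They included the lysosomal psap.S (2.58 ± 0.09) and the fibronectin mRNA fn1.S (-0.90 ± 0.07); the list had a camera adjusted p of 0.087 and adjusted p = 0.25 with an estimated correlation. Spike-in scaling had a mean log2 offset of -0.82 from the main scaling and gave 663 higher and 15648 lower, and limma on the attomolar values gave 706 and 7511.

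The oocyte pellet was higher than the cytosol for 9243 transcripts and lower for 8444, with 4368 higher and 2004 lower by at least 2-fold. The highest log2 fold changes were 5.86 ± 0.13 for sybu.L (gene6425), a kinesin adaptor, 5.79 ± 0.17 for ston1.S, 5.65 ± 0.30 for the zinc finger mRNA znf516.S, 5.62 ± 0.21 for dazl.L, a germ cell RNA-binding protein, and 5.58 ± 0.18 for ddx25.L, a germ plasm helicase. Levels of sybu.L were 212 ± 17.4 CPM in the pellet and 3.64 ± 0.783 in the cytosol (SD, n = 3). Its adjusted p was 1.7e-18. The lowest values were -2.59 ± 0.14 for parp2.L, -2.10 ± 0.08 for lrwd1.L, an origin recognition partner, -2.09 ± 0.08 for xrn2.L, a nuclear exonuclease, -2.04 ± 0.11 for plekha4.S and -2.02 ± 0.08 for ssx2ip.L. The vegetal and germ plasm list had 32 of 37 members higher and 2 lower (32 and 3 adjusted over the list alone), with a median of 3.29. Spike-in scaling gave 1.53 as median with 27 higher and 4 lower, and limma on attomolar values 1.39 with 24 and 4; the list had a camera adjusted p of 1.1e-17 and adjusted p = 0.21 with an estimated correlation. Within it the TGF-beta ligand gdf1.S (gene50666) stood at 4.74 ± 0.15, vegt.L, a transcription factor, at 3.0 ± 0.10, wnt11b.L at 4.97 ± 0.14 and velo1.L at 2.83 ± 0.10. Of 41 listed follicle cell markers, here and in eggs, the 23 tested were those past the low-count filter, which pellet libraries alone can satisfy. Follicle cell markers had 19 of 23 members higher and 0 lower (19 and 0 adjusted over the list alone), with a median of 3.29 and 2.99 with 1 member at 0 in a group set to the bound. Spike-in scaling gave 1.58 as median with 13 higher and 7 lower, and limma on attomolar values 1.06 with 12 and 7. Of these hsd3b1.L, a steroid dehydrogenase, was at 4.74 ± 0.27; the list had a camera adjusted p of 2.1e-04 and adjusted p = 0.20 with an estimated correlation. Cytosolic ribosomal protein mRNAs had 121 of 124 members higher and 1 lower (121 and 1 adjusted over the list alone), with a median of 1.34. Spike-in scaling gave -0.41 as median with 0 higher and 53 lower, and limma on attomolar values -0.66 with 0 and 64. An example is rps7.S (2.16 ± 0.08); the list had a camera adjusted p of 1.3e-28 and adjusted p = 0.25 with an estimated correlation. Oxidative phosphorylation mRNAs had 117 of 122 members higher and 0 lower (117 and 0 adjusted over the list alone), with a median of 1.28. Spike-in scaling gave -0.48 as median with 2 higher and 59 lower, and limma on attomolar values -0.71 with 1 and 72. The list holds cox4i2.S (2.35 ± 0.09); the list had a camera adjusted p of 3.1e-24 and adjusted p = 0.25 with an estimated correlation. Glycolysis enzymes had 25 of 31 members higher and 0 lower (26 and 0 adjusted over the list alone), with a median of 0.69. Spike-in scaling gave -1.08 as median with 2 higher and 27 lower, and limma on attomolar values -1.34 with 2 and 27. Both homeologs of phosphoglycerate mutase, pgam1.L (4.07 ± 0.11) and pgam1.S (3.26 ± 0.07), belong to it; the list had a camera adjusted p of 2.8e-07 and adjusted p = 0.25 with an estimated correlation. The proteasome list had 54 of 64 members higher and 4 lower (54 and 5 adjusted over the list alone), with a median of 0.57. Spike-in scaling gave -1.18 as median with 0 higher and 60 lower, and limma on attomolar values -1.46 with 0 and 60; the list had a camera adjusted p of 9.7e-09 and adjusted p = 0.25 with an estimated correlation. Maternal transcription factor and Wnt axis mRNAs had 13 of 63 members higher and 39 lower (13 and 40 adjusted over the list alone), with a median of -0.44. Spike-in scaling gave -2.20 as median with 5 higher and 57 lower, and limma on attomolar values -2.53 with 5 and 56. They included vegt.S (2.55 ± 0.07) and gsk3a.L, a kinase (-1.60 ± 0.07); the list had a camera adjusted p of 7.7e-04 and adjusted p = 0.25 with an estimated correlation. The mean offset with spike-in scaling was -1.76, leaving 1010 higher and 21489 lower, and limma on attomolar values left 866 and 21654.

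Between oocyte ER and pellet, 8018 transcripts were higher in the ER and 7274 in the pellet. Highest on the log2 scale were the uncertain model ccdc50.L (2.59 ± 0.36), bicra.S (1.87 ± 0.13), spata13.S (1.73 ± 0.09) and the transcription factor mRNAs tfap2c.S (1.72 ± 0.09) and foxi2.S (1.65 ± 0.09). On the pellet side were grip2.L at -5.32 ± 0.20, ston1.S at -4.91 ± 0.16, pgat.L at -4.35 ± 0.13, dazl.L at -4.35 ± 0.20 and gdf1.S (gene50666) at -4.11 ± 0.15. Apart from ston1.S these belong to the vegetal and germ plasm list. Animal pole RNAs had 10 of 12 members higher and 2 lower (10 and 2 adjusted over the list alone), with a median of 0.84. Spike-in scaling gave 1.77 as median with 11 higher and 0 lower, and limma on attomolar values 2.27 with 12 and 0. Both homeologs of the transcription factor grhl1 were among them, grhl1.L at 1.45 ± 0.07 and grhl1.S at 1.39 ± 0.07; the list had a camera adjusted p of 1.6e-04 and adjusted p = 0.25 with an estimated correlation. Glycolysis enzymes had 0 of 31 members higher and 29 lower (0 and 29 adjusted over the list alone), with a median of -0.88. Spike-in scaling gave 0.074 as median with 4 higher and 2 lower, and limma on attomolar values 0.49 with 12 and 2. Its member pgam1.L was at -3.29 ± 0.11; the list had a camera adjusted p of 3.3e-13 and adjusted p = 0.21 with an estimated correlation. Cytosolic ribosomal protein mRNAs had 0 of 124 members higher and 122 lower (0 and 122 adjusted over the list alone), with a median of -1.03. Spike-in scaling gave -0.084 as median with 7 higher and 11 lower, and limma on attomolar values 0.31 with 17 and 1. Members rps7.S and rps3a.L were at -1.84 ± 0.08 and -1.75 ± 0.09; the list had a camera adjusted p of 4.8e-36 and adjusted p = 0.25 with an estimated correlation. Meiotic maturation and cell cycle mRNAs had 61 of 113 members higher and 20 lower (61 and 20 adjusted over the list alone), with a median of 0.23. Spike-in scaling gave 1.16 as median with 100 higher and 1 lower, and limma on attomolar values 1.64 with 106 and 0. The kinase mRNA aurkb.S was at 1.63 ± 0.09 and the replication helicase mRNA mcm3.L at -1.64 ± 0.07; the list had a camera adjusted p of 0.0017 and adjusted p = 0.43 with an estimated correlation. The split moved to 17148 higher and 1483 lower with spike-in scaling (mean offset 0.94), to 19484 and 930 with limma on attomolar values, and to 5775 and 9345 with library size alone.

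In eggs, 4772 transcripts were higher in the ER than the cytosol and 5640 lower. The highest log2 fold changes were 6.60 ± 0.43 for the uncertain model ccdc50.L, 4.17 ± 0.11 for spata13.S, 4.12 ± 0.09 for ctsv.L (gene13520), a lysosomal protease, 3.75 ± 0.10 for cldn6.1.S, a tight junction protein, and 3.60 ± 0.12 for slc18a2.L, a vesicular monoamine transporter. The ctsv.L level was 257 ± 14 CPM in the ER against 14.7 ± 2.42 in the cytosol (SD, n = 3). Its adjusted p was 2.5e-18. The lowest were -2.45 ± 0.14 for parp2.L, -1.80 ± 0.34 for smad4.1.S, -1.58 ± 0.10 for the glycolytic gapdh.S, -1.35 ± 0.08 for the dynein chain dnah9.S and -1.32 ± 0.07 for sptan1.S. Secreted ligands and extracellular proteins had 29 of 72 members higher and 8 lower (29 and 9 adjusted over the list alone), with a median of 0.34. Spike-in scaling gave -1.45 as median with 5 higher and 54 lower, and limma on attomolar values -1.44 with 5 and 50. Both cathepsin B mRNAs, ctsb.L (3.26 ± 0.07) and ctsb.S (2.54 ± 0.06), belong to it; the list had a camera adjusted p of 1.3e-05 and adjusted p = 0.051 with an estimated correlation. Membrane receptors and adhesion proteins had 49 of 130 members higher and 22 lower (50 and 23 adjusted over the list alone), with a median of 0.13. Spike-in scaling gave -1.65 as median with 4 higher and 109 lower, and limma on attomolar values -1.59 with 4 and 107. They included the syndecan sdc4.S (2.65 ± 0.09) and the Notch ligand dll1.L (-2.35 ± 0.20); the list had a camera adjusted p of 2.1e-04 and adjusted p = 0.27 with an estimated correlation. Animal pole RNAs had 8 of 12 members higher and 1 lower (8 and 1 adjusted over the list alone), with a median of 0.69. Spike-in scaling gave -1.09 as median with 1 higher and 10 lower, and limma on attomolar values -1.10 with 1 and 9. Here grhl1.S was at 2.40 ± 0.08 and foxi2.S at 2.10 ± 0.09; the list had a camera adjusted p of 1.7e-05 and adjusted p = 0.21 with an estimated correlation. Histone mRNAs had 19 of 31 members higher and 0 lower (20 and 0 adjusted over the list alone), with a median of 0.42. Spike-in scaling gave -1.36 as median with 0 higher and 28 lower, and limma on attomolar values -1.38 with 0 and 28; the list had a camera adjusted p of 5.9e-06 and adjusted p = 0.30 with an estimated correlation. Ribosomal protein mRNAs of the cytosolic ribosome had 16 of 124 members higher and 68 lower (17 and 70 adjusted over the list alone), with a median of -0.27. Spike-in scaling gave -2.05 as median with 0 higher and 124 lower, and limma on attomolar values -2.09 with 0 and 124. Those lower included rps2.L (-1.38 ± 0.12) and rpsa.L (-0.94 ± 0.07); the list had a camera adjusted p of 3.2e-05 and adjusted p = 0.60 with an estimated correlation. Follicle cell markers had 6 of 23 members higher and 0 lower (6 and 0 adjusted over the list alone), with a median of 1.27 and 1.07 with 2 members at 0 in a group set to the bound. Spike-in scaling gave -0.25 as median with 2 higher and 8 lower, and limma on attomolar values 0 with 3 and 9. Those called included cyp17a1.L, a steroid hydroxylase (2.43 ± 0.08); the list had a camera adjusted p of 0.013 and adjusted p = 0.25 with an estimated correlation. Under spike-in scaling the mean offset was -1.78, which left 140 transcripts higher and 24034 lower, against 157 and 23987 with limma on attomolar values.

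In the egg pellet, 8919 transcripts were higher than in the cytosol and 8414 lower. Log2 fold changes were highest for ctsv.L (4.11 ± 0.09), cldn6.1.S (3.92 ± 0.10), cldn6.1.L (3.90 ± 0.14), ctsv.S (3.77 ± 0.09) and selenop1.L, a secreted selenium carrier (3.73 ± 0.30). The lowest belonged to parp2.L (-2.87 ± 0.14), prr12.L (-1.79 ± 0.12), kiaa0232.L (-1.77 ± 0.09), casp8ap2.L (-1.75 ± 0.11) and ankrd12.S (-1.74 ± 0.11). Histone mRNAs had 26 of 31 members higher and 0 lower (26 and 0 adjusted over the list alone), with a median of 1.43. Spike-in scaling gave -0.54 as median with 1 higher and 18 lower, and limma on attomolar values -0.82 with 0 and 20. Examples are hist2h3d.L (1.74 ± 0.08) and hist2h2ab.S (1.37 ± 0.07); the list had a camera adjusted p of 1.2e-09 and adjusted p = 0.25 with an estimated correlation. Follicle cell markers had 19 of 23 members higher and 1 lower (19 and 1 adjusted over the list alone), with a median of 3.94 and 2.84 with 2 members at 0 in a group set to the bound. Spike-in scaling gave 1.98 as median with 14 higher and 7 lower, and limma on attomolar values 0.72 with 11 and 8. Among these, hsd3b1.L stood at 5.70 ± 0.23; the list had a camera adjusted p of 1.6e-04 and adjusted p = 0.20 with an estimated correlation. The hsd3b1.L level was 46.9 ± 11.8 CPM in the pellet and 0.898 ± 0.287 in the cytosol (SD, n = 3). Vegetal and germ plasm RNAs had 25 of 37 members higher and 6 lower (25 and 6 adjusted over the list alone), with a median of 0.96. Spike-in scaling gave -1.02 as median with 4 higher and 21 lower, and limma on attomolar values -1.39 with 2 and 24. Members included pgat.L (3.37 ± 0.12) and velo1.L (-1.0 ± 0.09); the list had a camera adjusted p of 1.1e-05 and adjusted p = 0.37 with an estimated correlation. Meiotic maturation and cell cycle mRNAs had 59 of 113 members higher and 37 lower (59 and 38 adjusted over the list alone), with a median of 0.27. Spike-in scaling gave -1.72 as median with 0 higher and 99 lower, and limma on attomolar values -2.14 with 0 and 105. Cyclin B1 mRNAs ccnb1.L and ccnb1.S were at 1.36 ± 0.12 and 1.51 ± 0.11 and the checkpoint kinase mRNA bub1.L at -1.19 ± 0.07; the list had a camera adjusted p of 0.021 and adjusted p = 0.54 with an estimated correlation. Of the fixed panel, mos.L, the maturation kinase, was at 0.16 ± 0.05, a direction that turned to -1.80 with spike-in scaling and -2.16 with limma on attomolar values. It was at 0.12 and no longer called without egg cytosol replicate 2. The ER chaperone mRNAs hspa5 and hspa5.S were at -0.36 ± 0.07 and -0.13 ± 0.05, the latter no longer called without egg cytosol replicate 2 (-0.13), egg pellet replicate 2 (-0.13) or egg pellet replicate 3 (-0.12). Spike-in scaling had a mean offset of -2.0 and gave 829 higher and 22629 lower, limma on attomolar values 584 and 23707.

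Between ER and pellet of eggs, 7625 transcripts were higher in the ER and 7945 in the pellet. The ER had the uncertain model ccdc50.L (3.78 ± 0.37), spata13.S (2.25 ± 0.10), aff1.L (1.95 ± 0.09), spata13.L (1.89 ± 0.08) and nemf.L (1.84 ± 0.15) as the highest log2 fold changes. In the pellet were dnmt1.S (-2.56 ± 0.12) and dnmt1.L (-2.34 ± 0.12), both for the maintenance DNA methyltransferase, ddx25.L (-2.51 ± 0.16), smad4.1.S (-2.19 ± 0.34) and the actin nucleator spire1.S (-2.10 ± 0.11). Histone mRNAs had 0 of 31 members higher and 24 lower (0 and 24 adjusted over the list alone), with a median of -0.75. Spike-in scaling gave -0.56 as median with 0 higher and 13 lower, and limma on attomolar values -0.39 with 1 and 10. The oocyte linker histone mRNA h1foo.L was at -1.45 ± 0.11 and h2afz.L at -1.21 ± 0.09; the list had a camera adjusted p of 7.6e-08 and adjusted p = 0.25 with an estimated correlation. Glycolysis enzymes had 0 of 31 members higher and 25 lower (0 and 25 adjusted over the list alone), with a median of -0.50. Spike-in scaling gave -0.29 as median with 0 higher and 7 lower, and limma on attomolar values 0.090 with 1 and 0. Lactate dehydrogenase ldhb.S was at -1.10 ± 0.07 and tpi1.L at -0.97 ± 0.07; the list had a camera adjusted p of 1.8e-06 and adjusted p = 0.27 with an estimated correlation. Follicle cell markers had 1 of 23 members higher and 19 lower (1 and 19 adjusted over the list alone), with a median of -1.99 and -1.98 with 1 member at 0 in a group set to the bound. Limma on attomolar values gave -0.72 as median with 1 higher and 9 lower; the list had a camera adjusted p of 0.0011 and adjusted p = 0.21 with an estimated correlation. With spike-in scaling (mean offset 0.22) the counts were 4517 and 3369, and with limma on attomolar values 10285 and 1391.

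What changed in each fraction with maturation was read by comparing eggs with oocytes. In the cytosol 4780 transcripts were higher in eggs and 4818 lower. The highest log2 fold changes were 4.36 ± 0.30 for znf516.S, 4.0 ± 0.17 for naga.S, a lysosomal glycosidase, 3.98 ± 0.17 for ston1.S, 3.94 ± 0.12 for sybu.L and 3.36 ± 0.12 for cnppd1.L. The lowest were -3.46 ± 0.08 for ctsv.L, -3.18 ± 0.11 for gadd45a.S, a stress response gene, -2.97 ± 0.07 for ctsb.L, -2.87 ± 0.10 for epcam.L, an adhesion protein, and -2.86 ± 0.10 for cldn6.1.S. Levels of ctsv.L were 162 ± 1.10 CPM in oocytes and 14.7 ± 2.42 in eggs (SD, n = 3). Its adjusted p was 3.3e-17. Vegetal and germ plasm RNAs had 30 of 37 members higher and 1 lower (30 and 1 adjusted over the list alone), with a median of 1.30. They included acsl1.L, a fatty acid ligase (2.57 ± 0.11), and dand5.L (-0.96 ± 0.06); the list had a camera adjusted p of 2.7e-20 and adjusted p = 0.21 with an estimated correlation. Oxidative phosphorylation mRNAs had 87 of 122 members higher and 5 lower (90 and 5 adjusted over the list alone), with a median of 0.45. Spike-in scaling gave 0.70 as median with 68 higher and 0 lower, and limma on attomolar values 0.94 with 81 and 0. Complex I subunit ndufs1.L was at 1.10 ± 0.06; the list had a camera adjusted p of 5.5e-17 and adjusted p = 0.25 with an estimated correlation. Glycolysis enzymes had 20 of 31 members higher and 2 lower (21 and 2 adjusted over the list alone), with a median of 0.40. Spike-in scaling gave 0.66 as median with 14 higher and 0 lower, and limma on attomolar values 0.89 with 14 and 0. Its member pgam1.S was at 1.92 ± 0.07; the list had a camera adjusted p of 2.4e-07 and adjusted p = 0.25 with an estimated correlation. Egg coat mRNAs had 7 of 11 members higher and 0 lower (8 and 0 adjusted over the list alone), with a median of 0.26. Spike-in scaling gave 0.52 as median with 3 higher and 0 lower, and limma on attomolar values 0.75 with 4 and 0. Egg coat protein zpd.L was at 0.73 ± 0.06; the list had a camera adjusted p of 0.0035 and adjusted p = 0.25 with an estimated correlation. Actin and tubulin cytoskeleton mRNAs had 33 of 73 members higher and 6 lower (33 and 6 adjusted over the list alone), with a median of 0.19. Spike-in scaling gave 0.44 as median with 21 higher and 0 lower, and limma on attomolar values 0.68 with 22 and 0. The Arp2/3 subunit arpc2.L was at 1.69 ± 0.13 and vinculin vcl.S at 1.68 ± 0.07; the list had a camera adjusted p of 5.5e-05 and adjusted p = 0.25 with an estimated correlation. Histone mRNAs had 0 of 31 members higher and 20 lower (0 and 21 adjusted over the list alone), with a median of -0.47. Spike-in scaling gave -0.21 as median with 0 higher and 2 lower, and limma on attomolar values -0.062 with 0 and 0; the list had a camera adjusted p of 2.8e-07 and adjusted p = 0.26 with an estimated correlation. The mean offset was 0.26 with spike-ins, which gave 2629 higher and 636 lower, against 3623 and 325 with limma on attomolar values and 5912 and 3821 with library size alone.

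In the ER, 3218 transcripts were higher in eggs than oocytes and 4184 lower. The highest log2 fold changes were 2.95 ± 0.16 for ston1.S, 2.83 ± 0.26 for znf516.S, 2.70 ± 0.16 for naga.S, 2.42 ± 0.19 for grip2.L and 2.42 ± 0.15 for gdf1.S (gene50666). The lowest were -3.25 ± 0.11 for gadd45a.S, -2.36 ± 0.12 for dnmt1.S, -2.18 ± 0.12 for dnmt1.L, -2.13 ± 0.08 for anks3.L and -2.0 ± 0.13 for the redox regulator txnip.L. The vegetal and germ plasm list had 28 of 37 members higher and 2 lower (28 and 4 adjusted over the list alone), with a median of 1.02. Spike-in scaling gave 0.32 as median with 15 higher and 7 lower, and limma on attomolar values 0.34 with 12 and 5. The reticulon rtn3.S was at 3.27 ± 0.17; the list had a camera adjusted p of 2.5e-21 and adjusted p = 0.21 with an estimated correlation. Membrane receptors and adhesion proteins had 50 of 130 members higher and 7 lower (51 and 7 adjusted over the list alone), with a median of 0.17. Spike-in scaling gave -0.53 as median with 3 higher and 53 lower, and limma on attomolar values -0.44 with 1 and 12. Ephrin efnb1.L was at 1.54 ± 0.09 and the Wnt receptor fzd4.S at -0.96 ± 0.09; the list had a camera adjusted p of 2.0e-07 and adjusted p = 0.21 with an estimated correlation. Meiotic maturation and cell cycle mRNAs had 21 of 113 members higher and 55 lower (22 and 61 adjusted over the list alone), with a median of -0.19. Spike-in scaling gave -0.89 as median with 0 higher and 95 lower, and limma on attomolar values -0.91 with 0 and 71. The kinase aurka.S was at -1.45 ± 0.09 and ccne1.S at -1.24 ± 0.08; the list had a camera adjusted p of 2.7e-05 and adjusted p = 0.29 with an estimated correlation. Spike-in scaling, with a mean offset of -0.70, gave 205 higher and 15894 lower, and limma on attomolar values gave 183 and 6392.

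In the pellet, 5775 transcripts were higher in eggs and 5544 lower. Highest log2 fold changes were 1.98 ± 0.11 for the transcription factor mafb.S, 1.63 ± 0.09 for stil.L, a centriole duplication factor, 1.62 ± 0.10 for h2afx.L (gene13554), 1.56 ± 0.10 for the autophagy protease atg4c.L and 1.55 ± 0.06 for the G protein gna11.S. The lowest were -2.58 ± 0.10 for gadd45a.S, -1.91 ± 0.08 for the Polycomb protein cbx2.S, -1.86 ± 0.08 for the potassium channel kcnj5.L, -1.86 ± 0.13 for cnksr2.L and -1.84 ± 0.12 for the nuclear receptor nr4a1.L. For ribosomal protein mRNAs there were 1 of 124 members higher and 109 lower (1 and 110 adjusted over the list alone), with a median of -0.57. Spike-in scaling gave -0.56 as median with 0 higher and 39 lower, and limma on attomolar values -0.52 with 0 and 12. Those lower included rpl32.L (-1.22 ± 0.08) and rpl6.L (-1.10 ± 0.06); the list had a camera adjusted p of 3.2e-24 and adjusted p = 0.25 with an estimated correlation. Vegetal and germ plasm RNAs had 3 of 37 members higher and 30 lower (4 and 30 adjusted over the list alone), with a median of -0.98. Limma on attomolar values gave -0.93 as median with 1 higher and 17 lower. Lower members included velo1.L (-1.74 ± 0.09) and efnb1.L (-1.58 ± 0.09); the list had a camera adjusted p of 2.5e-13 and adjusted p = 0.25 with an estimated correlation. Histone mRNAs had 19 of 31 members higher and 1 lower (19 and 1 adjusted over the list alone), with a median of 0.59. Spike-in scaling gave 0.62 as median with 12 higher and 1 lower, and limma on attomolar values 0.76 with 12 and 0. A core histone mRNA, hist1h2bj.S, was at 1.42 ± 0.06; the list had a camera adjusted p of 1.8e-06 and adjusted p = 0.29 with an estimated correlation. Animal pole RNAs had 9 of 12 members higher and 0 lower (9 and 0 adjusted over the list alone), with a median of 0.40. Spike-in scaling gave 0.46 as median with 4 higher and 0 lower, and limma on attomolar values 0.51 with 4 and 0. The transcription factors sox3.S and foxi2.L were at 1.46 ± 0.10 and 0.87 ± 0.07; the list had a camera adjusted p of 4.1e-05 and adjusted p = 0.21 with an estimated correlation. Follicle cell markers had 1 of 23 members higher and 4 lower (1 and 3 adjusted over the list alone), with a median of -0.12. Limma on attomolar values gave -0.0081 as median with 1 higher and 0 lower. Without oocyte pellet replicate 2 the median was 0.035. Among them hsd3b1.L was at 2.08 ± 0.17 and star.S, a steroid transport protein, at -1.25 ± 0.25; the list had a camera adjusted p of 0.76 and adjusted p = 0.84 with an estimated correlation. Spike-in scaling and limma on attomolar values kept the split near even, with 1417 higher and 1230 lower and 644 and 532.

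Whether the ER to cytosol difference itself changed with maturation was tested as an interaction. It was higher in eggs for 3226 transcripts and lower for 3823. The highest differences in log2 fold change were 3.76 ± 0.11 for ctsv.L, 3.58 ± 0.09 for ctsb.L, 3.57 ± 0.19 for cldn6.1.L, 3.43 ± 0.14 for cldn6.1.S and 2.92 ± 0.11 for the channel mRNA calhm2.S. Of ctsv.L, 38.6 ± 4.70% of the copies were in the oocyte ER and 52.6 ± 10.8% in the egg ER (the authors' percentages, SD, n = 3). The lowest were -2.92 ± 0.18 for exd2.L, -2.68 ± 0.20 for the RNA polymerase II subunit polr2a.L, -2.46 ± 0.13 for the microtubule protein map4.S, -2.42 ± 0.13 for smtn.S and -2.27 ± 0.13 for exd2.S. Oxidative phosphorylation mRNAs had 1 of 122 members higher and 85 lower (1 and 92 adjusted over the list alone), with a median of -0.65. Spike-in scaling gave -1.63 as median with 0 higher and 121 lower, and limma on attomolar values -1.86 with 0 and 120. The ATP synthase subunit atp5pf.S was at -1.55 ± 0.12; the list had a camera adjusted p of 7.1e-24 and adjusted p = 0.25 with an estimated correlation. Ribosomal protein mRNAs of the cytosolic ribosome had 1 of 124 members higher and 80 lower (2 and 88 adjusted over the list alone), with a median of -0.57. Spike-in scaling gave -1.54 as median with 0 higher and 120 lower, and limma on attomolar values -1.72 with 0 and 117. Large subunit member rpl10.L was at -1.24 ± 0.11; the list had a camera adjusted p of 2.8e-17 and adjusted p = 0.31 with an estimated correlation. Membrane receptors and adhesion proteins had 48 of 130 members higher and 12 lower (51 and 13 adjusted over the list alone), with a median of 0.27. Spike-in scaling gave -0.68 as median with 4 higher and 55 lower, and limma on attomolar values -0.90 with 1 and 42. Syndecan sdc4.S was at 2.64 ± 0.12 and the integrin itga5.L at 1.82 ± 0.09; the list had a camera adjusted p of 5.9e-06 and adjusted p = 0.25 with an estimated correlation. Histone mRNAs had 10 of 31 members higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 0.18. Spike-in scaling gave -0.79 as median with 0 higher and 15 lower, and limma on attomolar values -0.94 with 0 and 14. The variant h2afx.L (gene1655) was at 1.37 ± 0.11; the list had a camera adjusted p of 2.7e-04 and adjusted p = 0.41 with an estimated correlation. The mean offset of spike-in scaling was -0.96, giving 128 higher and 14862 lower, and limma on attomolar values gave 101 and 13285.

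The pellet to cytosol difference was higher in eggs for 6150 transcripts and lower for 6081. The highest were 3.97 ± 0.11 for ctsv.L, 3.53 ± 0.11 for calhm2.S, 3.45 ± 0.12 for sdc4.S, 3.43 ± 0.13 for stil.L and 3.39 ± 0.10 for fn1.S. The lowest were -5.47 ± 0.16 for sybu.L, -5.23 ± 0.22 for ston1.S, -5.09 ± 0.37 for znf516.S, -5.06 ± 0.22 for naga.S and -4.70 ± 0.15 for cnppd1.L. Of sybu.L, 78.6 ± 5.41% of the copies were in the oocyte pellet and 16.5 ± 9.80% in the egg pellet, against 4.46 ± 0.600% and 62.7 ± 6.74% in the cytosol (SD, n = 3). Vegetal and germ plasm RNAs had 2 of 37 members higher and 31 lower (2 and 31 adjusted over the list alone), with a median of -2.44. In it velo1.L was at -3.83 ± 0.13 and wnt11b.L at -3.71 ± 0.17; the list had a camera adjusted p of 5.7e-17 and adjusted p = 0.21 with an estimated correlation. For ribosomal protein mRNAs there were 2 of 124 members higher and 110 lower (2 and 111 adjusted over the list alone), with a median of -0.86. Its member rpl32.L was at -1.89 ± 0.11; the list had a camera adjusted p of 2.5e-21 and adjusted p = 0.27 with an estimated correlation. Histone mRNAs had 19 of 31 members higher and 1 lower (20 and 1 adjusted over the list alone), with a median of 0.94. Limma on attomolar values gave 0.72 as median with 11 higher and 0 lower. Its member hist1h2bj.S was at 2.15 ± 0.09; the list had a camera adjusted p of 1.3e-07 and adjusted p = 0.25 with an estimated correlation. Meiotic maturation and cell cycle mRNAs had 62 of 113 members higher and 30 lower (65 and 31 adjusted over the list alone), with a median of 0.48. Spike-in scaling gave 0.28 as median with 37 higher and 16 lower, and limma on attomolar values 0.19 with 33 and 9. The cyclin ccna1.L was at 2.69 ± 0.13, the replication inhibitor gmnn.L at 2.0 ± 0.08 and mcm2.L at -1.90 ± 0.10; the list had a camera adjusted p of 9.0e-05 and adjusted p = 0.32 with an estimated correlation. Animal pole RNAs had 10 of 12 members higher and 2 lower (10 and 2 adjusted over the list alone), with a median of 0.82. Spike-in scaling gave 0.59 as median with 3 higher and 1 lower, and limma on attomolar values 0.51 with 2 and 0. Its member sox3.S was at 2.91 ± 0.15; the list had a camera adjusted p of 2.6e-04 and adjusted p = 0.25 with an estimated correlation. Follicle cell markers had 1 of 23 members higher and 2 lower (1 and 0 adjusted over the list alone), with a median of 0.26. Spike-in scaling gave 0.11 as median with 1 higher and 0 lower, and limma on attomolar values -0.39 with 0 and 1; the list had a camera adjusted p of 0.80 and adjusted p = 0.88 with an estimated correlation. Without egg cytosol replicate 3 this median was -0.16. Spike-in scaling (mean offset -0.24) gave 1465 higher and 3205 lower, limma on attomolar values 672 and 2978, and library size alone 4910 and 7469.

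**Figure D2:**
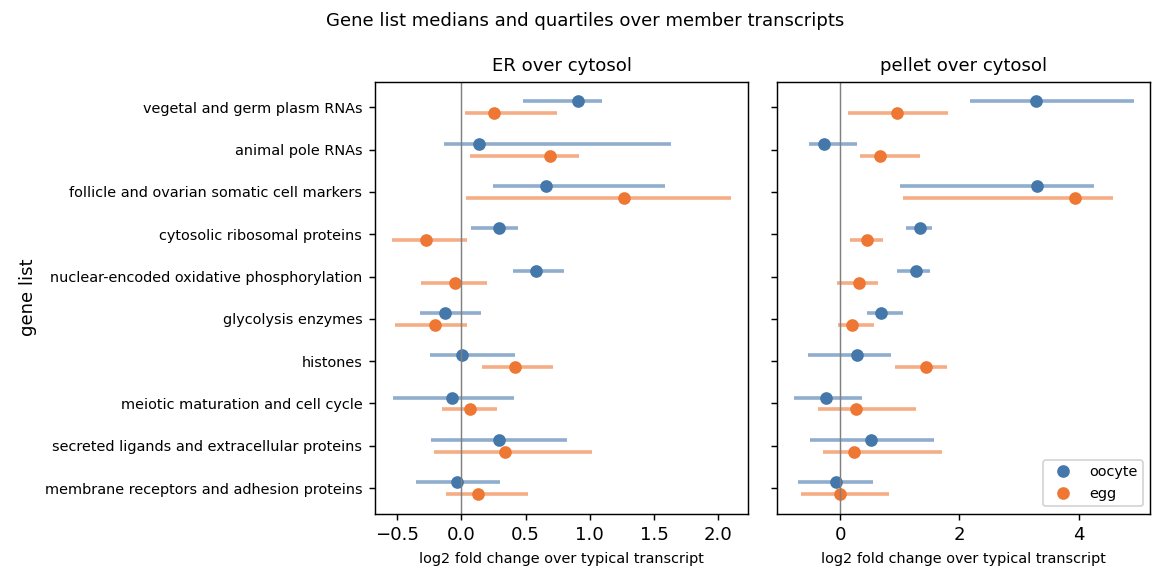
Median log2 fold change of 10 gene lists (y axis lists, x axis log2 fold change relative to the typical transcript) in ER over cytosol and pellet over cytosol, for oocytes and eggs. Points are list medians and lines their quartiles over member transcripts, which are not replicates. The vegetal and germ plasm list lies at 3.29 in the oocyte pellet and 0.96 in the egg pellet, the latter -1.02 with spike-in scaling.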

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

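Tests chosen only after the result was seen were those on dilution, decay and scaling of vegetal RNAs, on loss of mRNAs from egg libraries, on follicle cell RNA, on single libraries against matched transcripts, and the regrouping of libraries. The tests on sets matched for length and abundance were written beforehand.

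Differences between stages in the ER to cytosol contrast were tested as an interaction and passed for 3226 transcripts higher and 3823 lower in eggs. Single transcripts singled out by this interaction were ctsv.L (3.76 ± 0.11), ctsb.L (3.58 ± 0.09), cldn6.1.L (3.57 ± 0.19), cldn6.1.S (3.43 ± 0.14) and calhm2.S (2.92 ± 0.11) on the higher side. On the lower side were exd2.L (-2.92 ± 0.18), polr2a.L (-2.68 ± 0.20), map4.S (-2.46 ± 0.13), smtn.S (-2.42 ± 0.13) and exd2.S (-2.27 ± 0.13). Medians of histones and of membrane receptors and adhesion proteins were 0.18 and 0.27, which turned to -0.79 and -0.68 with spike-in scaling.

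The pellet to cytosol contrast differed between stages for 6150 transcripts higher and 6081 lower in eggs. Those higher included ctsv.L (3.97 ± 0.11), calhm2.S (3.53 ± 0.11), sdc4.S (3.45 ± 0.12), stil.L (3.43 ± 0.13) and fn1.S (3.39 ± 0.10). Those lower included sybu.L (-5.47 ± 0.16), ston1.S (-5.23 ± 0.22), znf516.S (-5.09 ± 0.37), naga.S (-5.06 ± 0.22) and cnppd1.L (-4.70 ± 0.15). Medians of animal pole RNAs, histones and meiotic maturation mRNAs were 0.82, 0.94 and 0.48.

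Vegetal and germ plasm RNAs fell in the pellet relative to the cytosol in eggs (median -2.44, camera adjusted p = 0.21 with an estimated correlation). Dilution of egg pellets by cytosol would need 89.2% of their RNA to be cytosolic, so that no transcript lay below a log2 value of -0.16 in egg pellet over cytosol. The 5th percentile of 8891 transcripts outside the list with a mean log2 CPM of at least 5 was -1.12, which leaves only a smaller dilution open. Decay of pellet-bound copies alone would leave the cytosol level unchanged, while the list median there was 1.30 (quartiles 0.62 and 2.07). Decay beside a gain in the cytosol stays open. Scaling to the typical transcript does not account for the fall, the median with spike-ins being -2.67. Release of these RNAs from the pellet with maturation may be involved, a hypothesis found on these libraries and not itself tested. Fractionation that differed between stages cannot be separated from it in this design.

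Oxidative phosphorylation and ribosomal protein mRNAs moved towards the cytosol in eggs, relative to the ER (medians -0.65 and -0.57, camera adjusted p = 0.25 and 0.31 with an estimated correlation) and to the pellet (-0.94 and -0.86, adjusted p = 0.25 and 0.27). Both lists hold short transcripts, but in 10000 random sets matched on length and abundance the medians were -0.10 (95% range -0.19 to -0.0091) and -0.12 (-0.20 to -0.037) for the ER, and 0.025 (-0.13 to 0.20) and 0.12 (-0.061 to 0.29) for the pellet, with 0 of 10000 as low as the list in each case, but such sets take members as independent. With the list median set against its matched transcripts within each of 12 libraries, the shifts were -0.61 ± 0.06 and -0.37 ± 0.05 for the ER and -1.15 ± 0.07 and -1.16 ± 0.06 for the pellet (SE over libraries). So measured, the oxidative phosphorylation list was at -0.43 to -0.24 in oocyte cytosol and 0.21 to 0.22 in egg cytosol. In the ER it was at -0.048 to -0.014 and -0.11 to -0.049. The ribosomal list was at -0.21 to -0.19 and 0.16 to 0.23 in the cytosol. In the ER it was at -0.28 to -0.13 and -0.19 to -0.16. The ER shifts thus came mostly from the cytosol libraries. The pellet shifts came from the pellet libraries as well. There oxidative phosphorylation was at 0.40 to 0.48 in oocytes and -0.20 to -0.065 in eggs, ribosomal proteins at 0.76 to 0.79 and -0.096 to 0.072. An equal loss from every egg fraction cancels in these shifts. The cytosol list medians (the lower 0.32, lower quartile 0.13) cannot test it. Other technical causes, such as fractionation that differed between stages, may remain and cannot be separated from the stage in this design.

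Although the cells had been defolliculated, 19 of 23 follicle cell markers were higher in the pellet than in the cytosol at each stage relative to the typical transcript (camera adjusted p = 0.20 with an estimated correlation), against 13 (7 lower) in oocytes and 14 (7 lower) in eggs with spike-in scaling and 12 (7 lower) and 11 (8 lower) with limma on attomolar values. RNA of remaining follicle cells may be a source: 69.6% of markers (16 of 23) were above 2-fold in the pellet at both stages, between the 80% set for that reading and the 50% set against it, against 56.5% with spike-in scaling and 43.5% with limma, so the reading depends on the scale. The most abundant member of the list, cyp17a1.L, was at 127 ± 4.1 CPM in the oocyte pellet and 125 ± 5.47 in the egg pellet. In the cytosol it was at 56.3 ± 1.57 and 20.7 ± 1.32 CPM (SD, n = 3). With such cytosol levels it does not by itself point to follicle cells. Median levels over the list were 2.25 and 1.73 CPM in the pellet and 0.280 and 0.264 in the cytosol of oocytes and eggs, with 5 of 23 markers at 1 CPM or more in the cytosol of each stage. Of 41 listed markers only the 23 that passed the low-count filter were tested. A marker low in the cytosol can pass it through pellet libraries alone. These tallies therefore lean to the pellet and cannot decide the source. Of the list, 4 of 23 are also in another list used here, so the source stays open.

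Regrouping the libraries of each comparison into other groups of 3 and 3 made 10 splits, and 1 of the 10, the real one, gave as many calls. The real splits, fitted with edgeR on the groups compared alone, gave 12898 (oocyte ER vs cytosol), 17184 (oocyte pellet vs cytosol), 14475 (oocyte ER vs pellet), 9917 (egg ER vs cytosol), 16807 (egg pellet vs cytosol), 14438 (egg ER vs pellet), 10344 (cytosol egg vs oocyte), 6560 (ER egg vs oocyte), 10438 (pellet egg vs oocyte), 7210 (ER to cytosol shift) and 12209 (pellet to cytosol shift) calls. The highest of the other splits gave 0 in each comparison with edgeR. At an unadjusted p under 0.05 the highest others gave, in the same order, 552, 267, 368, 929, 195, 385, 448, 632, 591, 363 and 573. With 10 splits no share under 0.05 can be reached.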

How the results depend on the processing

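Leaving out 3 libraries that stood apart (egg ER 1, oocyte pellet 1 and egg pellet 1) was chosen after the data were seen, and the other alternatives before the data were examined. With DESeq2, library size alone, no low-count filter, groups compared alone, the additive replicate block, any single library left out or those 3 left out, the counts higher and lower in each of the 11 comparisons stayed within 1.5 times those reported, as did those of the replicate block by stage and number in the 8 comparisons it was run on. Called transcripts with single libraries left out ranged over 11446 to 12966 (oocyte ER vs cytosol), 16819 to 18058 (oocyte pellet vs cytosol), 14097 to 15703 (oocyte ER vs pellet), 9103 to 10498 (egg ER vs cytosol), 16504 to 17576 (egg pellet vs cytosol), 14354 to 15759 (egg ER vs pellet), 8293 to 9832 (cytosol egg vs oocyte), 6114 to 7699 (ER egg vs oocyte), 10205 to 11674 (pellet egg vs oocyte), 6107 to 7260 (the ER to cytosol shift) and 11609 to 12408 (the pellet to cytosol shift). Without the 3 libraries they were, in the same order, 13263, 17590, 15301, 10551, 17204, 14302, 10243, 6754, 10720, 7332 and 12119. Of 212 gene values named in the text, 210 kept direction and call with each library left out. The exceptions were in egg pellet vs cytosol: mos.L was no longer called without egg cytosol 2 (0.12) or without the low-count filter (0.11), and hspa5.S without egg cytosol 2 (-0.13), egg pellet 2 (-0.13) or egg pellet 3 (-0.12), or with those groups fitted alone (-0.12). Direction and call held for 212 with DESeq2, 212 with library size alone, 212 without the 3 libraries, 197 with spike-in scaling and 188 with limma on attomolar values. Of 60 list medians, 56 kept their sign with each library left out. Follicle markers turned in pellet egg vs oocyte without oocyte pellet 2 (0.035) and in the pellet to cytosol shift without egg cytosol 3 (-0.16), and ER shaping and storage lists in egg ER vs cytosol lay near 0 (-0.0045 and -0.0013) and had either sign, against -1.78 and -1.78 with spike-in scaling and -1.79 and -1.82 with limma on attomolar values. Spike-in scaling gave, higher and lower, 663 and 15648 (oocyte ER vs cytosol), 1010 and 21489 (oocyte pellet vs cytosol), 17148 and 1483 (oocyte ER vs pellet), 140 and 24034 (egg ER vs cytosol), 829 and 22629 (egg pellet vs cytosol), 4517 and 3369 (egg ER vs pellet), 2629 and 636 (cytosol egg vs oocyte), 205 and 15894 (ER egg vs oocyte), 1417 and 1230 (pellet egg vs oocyte), 128 and 14862 (the ER to cytosol shift) and 1465 and 3205 (the pellet to cytosol shift). Limma on log2 attomolar values gave, higher and lower in the same order, 706 and 7511, 866 and 21654, 19484 and 930, 157 and 23987, 584 and 23707, 10285 and 1391, 3623 and 325, 183 and 6392, 644 and 532, 101 and 13285, and 672 and 2978. Neither sets the typical transcript to no change, so by construction the whole distribution moves. Attomolar values also carry an exponent per library and the same total for each stage and replicate number, and limma is another test. Its moves can therefore not be put down to the spike-ins alone. Called genes named in the text, and medians of lists described there that passed the preset camera test, of the other sign with spike-in scaling and limma were, in oocyte ER vs cytosol, ER resident and translocon -0.60 and -0.42, cytosolic ribosomal proteins -0.51 and -0.37, mitochondrial ribosomal proteins -0.44 and -0.24 and nuclear-encoded oxidative phosphorylation -0.23 and -0.033; in oocyte pellet vs cytosol, cytosolic ribosomal proteins -0.41 and -0.66, glycolysis enzymes -1.08 and -1.34, nuclear-encoded oxidative phosphorylation -0.48 and -0.71 and proteasome -1.18 and -1.46; in oocyte ER vs pellet, cytosolic ribosomal proteins 0.31 (limma alone) and glycolysis enzymes 0.074 and 0.49; in egg ER vs cytosol, animal pole RNAs -1.09 and -1.10, follicle and ovarian somatic cell markers -0.25 (spike-in scaling alone), histones -1.36 and -1.38, membrane receptors and adhesion proteins -1.65 and -1.59, secreted ligands and extracellular proteins -1.45 and -1.44, cd74.L -0.40 and -0.42, g3bp1.S -0.79 and -0.78, lnpk.L -0.025 and -0.019, reep4.S -0.28 and -0.29, slc4a1.L -1.01 and -1.06 and zar1l.S -0.63 and -0.64. They were, further, in egg pellet vs cytosol, histones -0.54 and -0.82, meiotic maturation and cell cycle -1.72 and -2.14, vegetal and germ plasm RNAs -1.02 and -1.39, ccnb1.L -0.63 and -0.85, ccnb1.S -0.49 and -0.69, hist2h2ab.S -0.60 and -1.02, hist2h3d.L -0.26 and -0.51 and mos.L -1.80 and -2.16; in egg ER vs pellet, glycolysis enzymes 0.090 (limma alone); in ER egg vs oocyte, membrane receptors and adhesion proteins -0.53 and -0.44; in the ER to cytosol shift, histones -0.79 and -0.94 and membrane receptors and adhesion proteins -0.68 and -0.90. Of lists described that did not pass, the medians turned for secreted ligands in oocyte ER vs cytosol (-0.51 and -0.26), blood, immune and liver markers in egg ER vs cytosol (-1.34 and -1.33) and follicle markers in the pellet to cytosol shift (-0.39, limma alone).

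The RNA ratio of egg to oocyte was 1.53 in the cytosol for the median transcript but 1.13, with overlapping libraries, from TPM over spike-in TPM, 0.587 in the ER without the 20 most abundant transcripts, and 0.973 in the pellet for the median transcript. With single libraries left out the pellet ratio ran from 0.937 to 1.44. The ER to cytosol ratio of oocytes was 0.782 from TPM over spike-in TPM, 0.671 for the median transcript and 0.660 without the 20. In eggs it was 0.279 and 0.299 for the last 2, and the pellet to cytosol ratio 0.164 for the median transcript. Shares of RNA without the 20 were 51.9% (oocyte cytosol), 34.2% (oocyte ER), 65.1% (egg cytosol) and 19.5% (egg ER), and from TPM over spike-in TPM 36.8% (oocyte ER) and 26.2% (egg ER). The 20 hold ccdc50.L. Without them the mean ER sums were 19099 aM in oocytes and 11204 aM in eggs, against 29848 and 20238 aM with them. Over all transcripts with any value the median oocyte ER share was 31.3%.

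Of the 209 list tests, 113 passed at an adjusted p under 0.05 with camera's preset correlation and 0 with an estimated correlation (limma's camera, 37 at an unadjusted p under 0.05), while fry gave 170 and its mixed test 209. For the egg pellet against cytosol and ER, where pairing by number stayed uncertain, the replicate block by stage and number gave 17854 and 16212 called transcripts. The additive replicate block gave, with all comparisons ordered as above, 13092, 17905, 15593, 10861, 17520, 15813, 10089, 8034, 11795, 7527 and 12598, and changed no call of a gene named in the text. The cause of other changes was not tested. In simulated counts of the same depth and replicate number, 54.7% of 1.5-fold and 86.6% of 4-fold changes were recovered for oocyte ER vs cytosol, and 43.5% and 82.9% for the pellet to cytosol shift. Only 200 of 25938 transcripts were changed there, far fewer than were called in the data, so recovery in the data may differ.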

Other observations

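No test in this part was chosen after the result was seen, but which lists and genes are described was.

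In eggs, ER against cytosol, some of the fixed lists did not pass the camera test relative to the typical transcript, while most of their members were lower with spike-in scaling. ER shaping mRNAs had 13 of 40 members higher and 9 lower (14 and 9 adjusted over the list alone), with a median of -0.0045. Spike-in scaling gave -1.78 as median with 0 higher and 35 lower, and limma on attomolar values -1.79 with 0 and 35. Their members lnpk.L, which acts at ER tubule junctions, reep4.S and the reticulon rtn4.L were at 1.75 ± 0.06, 1.5 ± 0.06 and -0.60 ± 0.08; the list had a camera adjusted p of 0.11 and adjusted p = 0.27 with an estimated correlation, the mean being 0.21 and the test pointing up. The mRNAs for maternal mRNA storage and translation control had 29 of 94 members higher and 28 lower (30 and 29 adjusted over the list alone), with a median of -0.0013. Spike-in scaling gave -1.78 as median with 0 higher and 94 lower, and limma on attomolar values -1.82 with 0 and 94. Relative to the typical transcript zar1l.S was at 1.15 ± 0.08, the stress granule protein mRNA g3bp1.S at 0.99 ± 0.07 and sympk.S at -0.81 ± 0.07; the list had a camera adjusted p of 0.91 and adjusted p = 0.95 with an estimated correlation, the mean being -0.013 and the test pointing up. Blood, immune and liver markers had 2 of 8 members higher and 0 lower (2 and 0 adjusted over the list alone), with a median of 0.43. Spike-in scaling gave -1.34 as median with 0 higher and 5 lower, and limma on attomolar values -1.33 with 0 and 5. Of these cd74.L was at 1.37 ± 0.23 and slc4a1.L at 0.76 ± 0.08; the list had a camera adjusted p of 0.20 and adjusted p = 0.51 with an estimated correlation. With spike-in scaling, a mean offset of -1.78 in this comparison, lnpk.L, reep4.S, zar1l.S, g3bp1.S, cd74.L and slc4a1.L turned negative.

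In the pellet to cytosol shift between stages the same storage list had 30 of 94 members higher and 38 lower (31 and 38 adjusted over the list alone), with a median of -0.086. Spike-in scaling gave -0.30 as median with 4 higher and 26 lower, and limma on attomolar values -0.46 with 3 and 23. The deadenylation factors tob2.L (-3.19 ± 0.13) and cnot1.L (-2.22 ± 0.11) were lower in eggs, and btg4.L (1.82 ± 0.15) and the poly(A) polymerase papd4.S (1.5 ± 0.08) higher; the list had a camera adjusted p of 0.17 and adjusted p = 0.52 with an estimated correlation. ER shaping mRNAs there had 16 of 40 members higher and 13 lower (16 and 13 adjusted over the list alone), with a median of -0.087. Spike-in scaling gave -0.30 as median with 4 higher and 7 lower, and limma on attomolar values -0.58 with 4 and 6. Both reticulon 3 homeologs, also in the vegetal and germ plasm list, were lower, rtn3.S at -4.95 ± 0.22 and rtn3.L at -1.53 ± 0.09. List member kank1.L, whose role in ER shaping was not examined, was at 2.77 ± 0.11 and lnpk.L at 1.82 ± 0.08. The list had a camera adjusted p of 0.71 and adjusted p = 0.74 with an estimated correlation, the mean being 0.046 and the test pointing up. Oxidative phosphorylation mRNAs had 4 of 122 members higher and 104 lower (4 and 107 adjusted over the list alone), with a median of -0.94; the list had a camera adjusted p of 5.4e-19 and adjusted p = 0.25 with an estimated correlation.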
